A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

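Footprint and total RNA libraries were made from the same yeast strain grown with 0 or 10 µM added spermidine, 2 replicates of each, and were grouped by assay and spermidine from the sample titles. Per the labels' protocols, footprints came from filtered cells broken in a freezer mill, digested with RNase I and size-selected at 17 to 34 nucleotides, and RNA libraries came from 10 µg of total RNA fragmented at 70 °C for 15 min. The deposited table holds whole-number read counts per gene for the 8 libraries, which the authors made from their reads; the submitters' processing notes name cutadapt, Bowtie 1.2.2, Bowtie 1.1.2, edgeR and the builds R64 and sacCer3, with no role or order. Which part of a gene was counted, how reads that match several genes were treated and whether the counting used strand are not given in the sources used here. This matters for duplicated ribosomal protein, hexose transporter, glyceraldehyde-3-phosphate dehydrogenase and enolase genes, whose reads can move between copies, and for overlapping genes. Counts carry no position, so footprints on leaders and coding regions cannot be told apart.

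The table lists 5545 genes. The smallest count in each library was 1, so genes with a count of 0 in some library appear to have been left out of the table, and a gene that went from silent to expressed cannot be seen. Gene IDs were paired with symbols and R64 coordinates from a RefSeq gene table, which matched 5543 IDs and left 2 unmatched, YOL013W-A and YPR108W-A. A further 3 lines of the table named no gene and held no counts. The RNA of YPR108W-A was the most abundant entry of every RNA library; it stayed in the library totals. The 10 most abundant genes took 11.4% to 15.8% of a library's counts. Totals ran from 1786419 to 2884632 counts in RNA and from 3324344 to 7089928 in footprints. Replicates differed by more than counting noise (chi-square over degrees of freedom of 5.66 to 10.4), so no pair looked like a single library given in duplicate. The 0 µM libraries were deeper than the 10 µM libraries in both assays, and the RNA libraries were shallower than the footprint libraries. The labels give no sequencing batch.

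Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its minimum count of 10 and minimum total of 15, which left 5488. Composition factors were computed by the trimmed mean of M values over all 8 libraries. Changes under this scaling are relative to the typical gene, so a shift of all mRNA or all footprints together cannot be seen. One quasi-likelihood model with a coefficient for each of the 4 groups and no block was fitted to all 8 libraries, which leaves 4 residual degrees of freedom, and 3 contrasts were tested: footprints at 10 against 0 µM, RNA at 10 against 0 µM, and their difference, the change in translational efficiency. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 within a contrast. Standard errors were taken as the log2 change over the root of its F statistic. Group levels are means and SDs of CPM computed here over composition-adjusted totals, and ratio levels are means of footprint over RNA CPM of libraries with the same replicate number. These p-values compare 2 libraries with 2, and the 4 groups share 1 estimate of the spread.

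Before the data were examined, the samples, the tests, the alternatives, 30 gene lists and a rule for named genes were fixed. The rule takes, per contrast, the 12 largest rises and 12 largest falls among called genes whose replicates do not overlap between conditions, HOL1, SPE1 to SPE4, OAZ1, FMS1, LEU2 and URA3, and up to 4 members of each list with the smallest p. Non-overlap alone is common: it held for 72.6%, 60.2% and 52.8% of tested genes in footprints, RNA and efficiency, where chance gives 33.3%. Every called gene met it in each contrast, so the condition removed none and is no added check. For efficiency, both this non-overlap and limma on log2 ratios also match libraries by replicate number, which the labels do not state; the edgeR changes and their standard errors do not. Other list members that the text names, such as RPS22B in RNA or RPL1B in efficiency, were chosen after their values were seen. Lists with at least 5 tested members, 25 of the 30, were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and adjusted over lists within a contrast; as alternatives the correlation was estimated per list, and fry tested whether a list's genes moved 1 way. No list call in any contrast held with an estimated correlation, where the smallest adjusted p was 0.49 in footprints, 0.31 in RNA and 0.89 in efficiency. Some lists share members, and the list of 8 mitochondrially encoded proteins had no tested member. A list of proteins with runs of prolines needs coding sequences and was not analysed here. A further 4 lists were chosen after the results were seen and are used only in the closing part.

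Each test was run first on simulated counts with the real means, totals and spread, in which 200 genes changed. In footprints the edgeR test recovered 40.3% of genes changed 1.5-fold, 91.0% of those changed 2-fold and 97.0% of those changed 4-fold among 5477 genes, and 6.17% of its calls were false. For efficiency in the same simulation it recovered 9.0%, 71.6% and 97.0%, with 4.84% false. In RNA it recovered 31.8%, 85.1% and 100% among 5478 genes, with 6.49% false. With no gene changed, it called 1, 0 and 1 genes in footprints, RNA and efficiency. A list of 30 genes changed 1.5-fold was called in footprints with the preset correlation (camera adjusted p 1.2e-57) and with an estimated one (0.0015). None of 29 unchanged lists was called. Genes were simulated independently of each other, so this does not show how often the list test calls unchanged lists of correlated genes. In the data the estimated correlation in footprints was 0.52 for cytosolic ribosomal proteins and highest, 0.58, for Gcn4-responsive genes. Alternatives were other scalings (relative log expression factors, totals only, factors within each assay), no filter or a mean count of at least 100, DESeq2 1.42.0, limma voom, the older edgeR dispersion method, each assay alone, a block for the replicate number, limma on log2 ratios with 0.5 CPM added, stricter thresholds, omission of each library in turn and, chosen after seeing the data, removal of a length trend within each assay. With a library left out, its group has 1 sample, which is assumed to vary like the others. No other splits of the samples were tested, since groups hold 2 libraries.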

Results

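Ribosome footprints and total RNA were sequenced from a budding yeast strain, Saccharomyces cerevisiae of mating type a, in which SPE1 and SPE2 were each replaced by LEU2. SPE1 encodes ornithine decarboxylase, which makes putrescine, and SPE2 encodes S-adenosylmethionine decarboxylase, which supplies the aminopropyl group of spermidine, so the strain depends on polyamines taken up from the medium. Cells grew at 30 °C in synthetic dextrose medium with 0 or 10 µM added spermidine, from an optical density of 0.025 to between 0.6 and 0.7. Ribosome profiling sequences the stretches of mRNA that ribosomes shield from nuclease, here 17 to 34 nucleotides long, so that a gene's footprint count follows how many ribosomes were on its mRNA. Each of the 4 groups (footprints or RNA, at 0 or 10 µM) held 2 libraries, 8 in all. Gene counts summed to between 1786419 and 2884632 reads per RNA library and between 3324344 and 7089928 reads per footprint library. The first principal component of log2 depth-scaled counts separated the assays (78.9% of the variance) and the second separated 0 from 10 µM in both assays (13.2%). Replicates correlated across genes with Pearson r of 0.983 and 0.984 for RNA and 0.990 and 0.987 for footprints. Genes are not independent replicates. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

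The deleted genes were near the bottom of every library. SPE1 had 4 to 15 reads per library, at 1.25 to 7.18 depth-scaled counts (CPM), and SPE2 had 3 to 62 reads, at 1.57 to 9.78 CPM. At most 3.97% of tested genes lay below SPE1 in a library and at most 11.2% lay below SPE2. The reads that remained on SPE2 were called lower at 10 µM in RNA (log2 change -1.46, edgeR adjusted p = 0.035), from 9.33 ± 0.64 to 3.35 ± 2.5 CPM (SD, n = 2). That call rested on few reads and was lost without either RNA replicate at 0 µM or without RNA replicate 1 at 10 µM, with values from -2.55 to -0.86 over the single-library omissions, and with each assay fitted alone (adjusted p 0.059). LEU2, the marker used for both deletions, held 973 ± 86 CPM in RNA at 0 µM and 1041 ± 30 at 10 µM, a log2 difference of 0.10 (edgeR adjusted p = 0.55). LEU2 footprints rose by 0.49 on the log2 scale (edgeR adjusted p = 0.0046). URA3, which is inactive in this strain through the ura3-52 allele, was called lower in RNA (log2 change -0.37, edgeR adjusted p = 0.049), a call kept in only 1 of the 8 omissions of a single library, over which the value ran from -0.45 to -0.29. The URA3 call was also lost in 7 of 11 other settings, among them both other scalings of all libraries, DESeq2 and limma voom (largest adjusted p 0.30).

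The study asked how low and high polyamine levels change translation, with HOL1 as its subject. HOL1 (YNR055C; chromosome XIV, 728426 to 730186 in the R64 assembly) encodes the high-affinity polyamine transporter of the plasma membrane. Its footprints fell 3.03-fold with spermidine, from 87.5 ± 10.7 to 29.0 ± 4.7 CPM (SD, n = 2), a log2 change of -1.60 (SE 0.15, edgeR adjusted p = 5.9e-05). Its mRNA fell 1.87-fold, from 99.3 ± 2.6 to 53.0 ± 2.6 CPM, a log2 change of -0.90 (SE 0.15, edgeR adjusted p = 0.0026). The footprint to mRNA ratio, taken as translational efficiency, went from 0.884 to 0.549, a log2 difference of -0.70 (SE 0.21) that did not pass the test over all genes (edgeR adjusted p = 0.13). Across the 8 fits that each left out 1 library, the difference in HOL1 efficiency lay between -0.86 and -0.53. The counts carry no positions, so footprints on the leader of HOL1 mRNA were not analysed here.

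**Figure D1:**
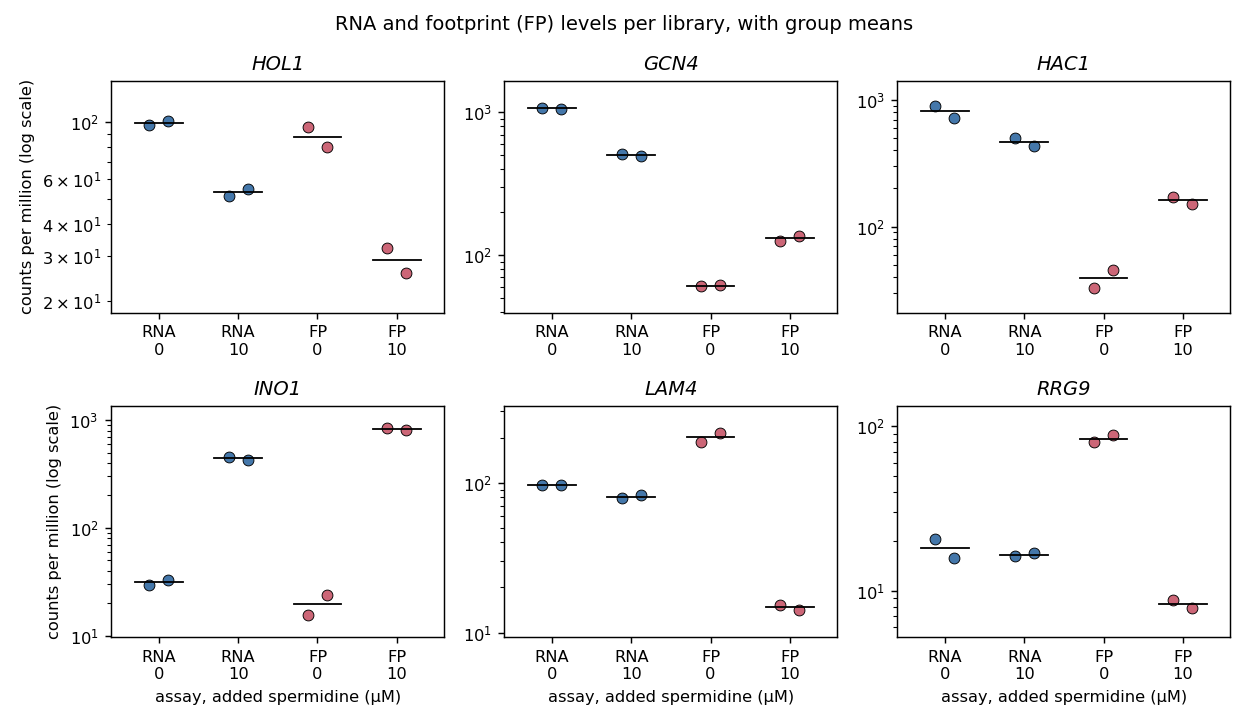
CPM (log scale) of 6 genes in each of the 8 libraries, for RNA (blue) and footprints (FP, red) at 0 and 10 µM added spermidine. Each point is a library and each line a group mean. HOL1 fell in both assays, GCN4 and HAC1 fell in RNA and rose in footprints, INO1 rose in both, and LAM4 and RRG9 fell in footprints, with RNA differences of -0.26 and -0.13 on the log2 scale that were not called.

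In footprints, spermidine raised 1025 genes and lowered 1093 of the 5488 tested, 2118 in all (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). Here, as in RNA and efficiency, rises and falls are relative to the typical gene, whose median log2 change in footprints was -0.017 after scaling. INO1, which encodes inositol-3-phosphate synthase, rose 40.9-fold, from 19.8 ± 5.8 to 825 ± 16 CPM (SD, n = 2; edgeR adjusted p = 3.6e-07). RPL22B, 1 of the 2 genes for ribosomal protein L22, rose 8.52-fold, from 11.5 ± 0.62 to 98.7 ± 6.2 CPM (edgeR adjusted p = 1.6e-06). AZR1, a plasma membrane transporter of the major facilitator superfamily, fell 28.7-fold, from 68.3 ± 9.2 to 2.32 ± 0.18 CPM (edgeR adjusted p = 1.6e-06). LAM4, a sterol transfer protein at contacts of the endoplasmic reticulum with the plasma membrane, fell 13.7-fold, from 202 ± 19 to 14.8 ± 0.82 CPM (edgeR adjusted p = 3.6e-07). The other largest rises were in PBI1 (log2 change 4.03), RRT5 (3.80), HES1 (3.66), YPR145C-A (3.32), the alcohol dehydrogenase genes ADH4 (2.87) and ADH5 (2.84), SPG3 (2.82), the vacuolar alpha-mannosidase gene AMS1 (2.78), DCG1 (2.76) and URA10 (2.76). RRT5, HES1 and SPG3 started from 0.658, 0.717 and 1.67 CPM at 0 µM, so the sizes of their changes are imprecise. The other largest falls were in YER053C-A (-3.96), ARV1 (-3.53), the aquaporin gene AQY2 (-3.44), the mitochondrial genome maintenance gene RRG9 (-3.35), the spore membrane gene SMA2 (-2.84), YGR146C-A (-2.77), the hexose transporter gene HXT7 (-2.60), SMA1 (-2.56), CNM1 (-2.43) and YGL235W (-2.42).

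Several of these footprint values carry a limit of their own. ARV1 stood at 202 ± 215 CPM at 0 µM, and its log2 change ran from -4.32 to -1.48 over the omissions of a single library, with the smallest size without footprint replicate 2 at 0 µM. The YGL235W call was lost without that library and without footprint replicate 1 at 10 µM (range -3.65 to -1.24), and the SMA1 call without footprint replicate 2 at 0 µM or either footprint replicate at 10 µM (range -3.30 to -2.16). YGL235W lies opposite MTO1 and AQY2 overlaps YLL053C on the same strand, and HXT7 has a near-identical copy in HXT6, so reads of these genes may be shared and their own values are uncertain. The count of 2118 fell to 1395 when footprint replicate 2 at 0 µM was left out.

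Among genes of polyamine transport and its regulators, footprints of 7 of the 14 tested members fell and 1 rose (1 rose and 8 fell when adjusted over the list alone). Besides HOL1, the 4 drug:proton antiporter genes TPO2 (log2 change -1.21), TPO1 (-0.97), TPO4 (-0.83) and TPO3 (-0.79), which export polyamines, fell. The kinase genes SKY1 (-0.41) and PTK2 (-0.37) fell too, while AGP2 (0.84), which encodes a plasma membrane regulator of polyamine and carnitine uptake, rose. TPO3, SKY1, PTK2 and AGP2 were named after their values were seen. SKY1 and PTK2 lost their calls with DESeq2, with the length trend removed and without either footprint replicate at 0 µM, SKY1 also without footprint replicate 1 and PTK2 without footprint replicate 2 at 10 µM and with a mean count of at least 100 (largest adjusted p 0.15 and 0.25). The median change of the list was -0.39, which did not pass the test against other genes (camera adjusted p = 0.054, and adjusted p = 0.49 with an estimated correlation). In the list for polyamine synthesis, breakdown and antizyme, 3 of 9 members rose and 1 fell (the same numbers when adjusted over the list alone; median 0.25, camera adjusted p = 0.77). SPE3, spermidine synthase, fell from 413 ± 28 to 314 ± 7.1 CPM (log2 change -0.39, edgeR adjusted p = 0.010), a call lost without footprint replicate 1 at either concentration (largest adjusted p 0.088). OAZ1, the antizyme made through a polyamine-dependent frameshift, rose from 20.4 ± 2.2 to 32.6 ± 0.82 CPM (0.69, edgeR adjusted p = 0.024), a call lost with DESeq2, and without footprint replicate 2 at 0 µM or either footprint replicate at 10 µM (largest adjusted p 0.12). PAA1 (0.45) and CAR1 (0.40) were the other 2 that rose. PAA1 lost its call without footprint replicate 1 at 0 µM or replicate 2 at 10 µM (largest adjusted p 0.069), and CAR1 in 6 of the 8 omissions (largest adjusted p 0.22). CAR1 also lost it with library totals, no filter, DESeq2 and the length trend removed (adjusted p 0.067, 0.051, 0.11 and 0.10). SPE4, spermine synthase, and FMS1, polyamine oxidase, differed by 0.25 and -0.47 on the log2 scale, which did not pass the test (edgeR adjusted p = 0.38 and 0.29). Of the 3 genes with programmed plus-one frameshifts, OAZ1 and ABP140 (0.38) rose and EST3 (-0.25) was not called (2 rose when adjusted over the list alone). ABP140 lost its call with DESeq2 and without footprint replicate 1 at 0 µM or either footprint replicate at 10 µM (largest adjusted p 0.15). Of the 4 genes for eIF5A, the elongation factor that carries the spermidine-derived residue hypusine, and its modifying enzymes, LIA1, deoxyhypusine hydroxylase, fell by 0.48 on the log2 scale (1 fell when adjusted over the list alone), a call lost without either footprint replicate at 0 µM or replicate 1 at 10 µM (largest adjusted p 0.17). HYP2, the main eIF5A gene, differed by -0.03. Differences in this list ran from -0.48 to 0.71, and no member was called higher.

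Ergosterol synthesis was the list with the largest share of genes that rose in footprints, 21 of 25 with none falling (21 when adjusted over the list alone; median log2 change 0.81). ERG3 (2.09), ERG6 (1.70), ERG25 (1.34) and ERG26 (1.33), enzymes of the late sterol steps, rose most clearly (camera adjusted p = 1.0e-15 for the list, adjusted p = 0.49 with an estimated correlation). Glycolysis and fermentation had 10 of 20 genes higher and none lower (11 when adjusted over the list alone; median 0.47). The glyceraldehyde-3-phosphate dehydrogenase genes TDH2 (2.19) and TDH1 (1.5) and the enolase genes ENO1 (1.22) and ENO2 (1.22) were among them (camera adjusted p = 6.7e-06, adjusted p = 0.49 with an estimated correlation). These are near-identical paralogs, so how their reads were divided is uncertain. Genes of amino acid synthesis that respond to Gcn4 rose in 18 of 39 cases and fell in 7 (19 and 8 when adjusted over the list alone; median 0.28, camera adjusted p = 0.0012, adjusted p = 0.62 with an estimated correlation). SER3 of serine synthesis (2.39), SNZ1 of vitamin B6 synthesis (1.92), and the arginine pathway genes ARG1 (1.38) and CPA1 (1.32) were the clearest. SER3 overlaps the annotated transcript SRG1, whose strand was not established here, so its own value is uncertain. In pantothenate and coenzyme A synthesis, 5 of 12 genes rose and none fell (6 when adjusted over the list alone; median 0.38, camera adjusted p = 0.018, adjusted p = 0.49 with an estimated correlation), led by CAB2 (1.74), the aldehyde dehydrogenase gene ALD2 (1.72) and ECM31 (0.97). Nitrogen catabolite repressed genes rose in 9 of 29 cases and fell in 1 (8 and 1 when adjusted over the list alone; median 0.30). UGA1 (2.51) and UGA2 (1.11), enzymes of 4-aminobutyrate use, and GLN1 (0.94), glutamine synthetase, rose, and the proline permease gene PUT4 (-2.03) fell. The list's call (camera adjusted p = 0.038, adjusted p = 0.60 with an estimated correlation) was lost without footprint replicate 2 at 0 µM, where its median was 0.12.

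Among cytosolic ribosomal protein genes 72 of 138 fell and 8 rose (77 and 9 when adjusted over the list alone; median -0.35, camera adjusted p = 6.0e-05, adjusted p = 0.65 with an estimated correlation). RPL6A (-0.93) fell, while RPL22B (3.09), RPS22B (1.53) and RPL9B (1.41), each 1 gene of a duplicated pair, rose. Translation initiation and elongation factors fell in 20 of 38 cases and rose in 3 (21 and 3 when adjusted over the list alone; median -0.36). TIF11, initiation factor 1A (-1.04), SUP35, a release factor (-0.91), NEW1 (-0.84) and YEF3, elongation factor 3 (-0.72), fell, and HCR1 (0.50), TIF4632 (0.47) and CAM1 (0.31) rose (camera adjusted p = 5.3e-04, adjusted p = 0.49 with an estimated correlation). TIF4632 and CAM1 lost their calls without footprint replicate 2 at 0 µM or either footprint replicate at 10 µM, CAM1 also without footprint replicate 1 at 0 µM, with library totals, DESeq2 and the length trend removed (largest adjusted p 0.11 and 0.16). Of 75 ribosome biogenesis genes, 44 fell and 1, HAS1 (0.52), rose (50 and 1 when adjusted over the list alone; median -0.44, camera adjusted p = 3.1e-07, adjusted p = 0.56 with an estimated correlation), with BRX1 (-1.05), KRR1 (-1.01) and ESF1 (-0.89) among those that fell. HAS1 lost its call without footprint replicate 2 at either concentration (largest adjusted p 0.068). In the nuclear-encoded respiratory chain and ATP synthase, 13 of 33 genes fell and none rose (13 when adjusted over the list alone; median -0.19, camera adjusted p = 0.0014, adjusted p = 0.60 with an estimated correlation), with NDE1, an NADH dehydrogenase (-1.60), CYT1, cytochrome c1 (-1.07), and RIP1, the Rieske protein (-0.96). Plasma membrane transporters of amino acids and sugars fell in 11 of 25 cases and rose in 5 (12 and 5 when adjusted over the list alone; median -0.38, camera adjusted p = 0.018, adjusted p = 0.49 with an estimated correlation). The methionine permease gene MUP1 (-1.96) and the amino acid permease genes AGP1 (-1.61) and GNP1 (-1.15) were among those that fell.

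Other lists did not pass the footprint list test. Iron uptake genes fell in 8 of 27 cases and rose in 4 (9 and 4 when adjusted over the list alone; median -0.20, camera adjusted p = 0.054), with FRE1 (-1.61), ARN1 (-1.34), the heme oxygenase gene HMX1 (-1.23) and the ferroxidase gene FET3 (-1.21) lower. Oxidative stress defence genes rose in 13 of 25 cases and fell in 4 (15 and 5 when adjusted over the list alone; median 0.43, camera adjusted p = 0.060). The peroxiredoxin gene TSA2 (2.47) rose and the catalase gene CTT1 (-1.27) fell. Methionine and S-adenosylmethionine genes rose in 8 of 25 cases and fell in 5 (8 and 7 when adjusted over the list alone; median 0.12), with MET3 (1.37) and MET17 (1.16) higher. Genes with described regulatory upstream open reading frames rose in 6 of 22 cases and fell in 8 (the same when adjusted over the list alone; median 0.03), among them GCN4 (1.1) and HAP4 (-1.29). Heat shock proteins and chaperones rose in 10 of 30 cases and fell in 6 (median -0.01), with SSA1 (0.73) and HSP60 (0.72) higher and HSP42 (-0.85) lower. General stress and reserve carbohydrate genes rose in 6 and fell in 6 of 30 (median 0.01), with GPD1 (0.81) higher and DDR2 (-2.01) lower. Cell wall genes rose in 10 and fell in 9 of 28 (median -0.03), with CWP1 (1.88) and PIR3 (1.72) higher and SCW10 (-1.27) lower. Citric acid cycle genes rose in 5 and fell in 3 of 20 (CIT2, 1.09), and phosphate acquisition genes rose in 5 and fell in 1 of 16 (VTC3, 0.84). Autophagy genes rose in 7 and fell in 3 of 24 (ATG19, 1.15), and mitochondrial ribosomal protein genes rose in 14 and fell in 4 of 73 (MRPS12, -0.81). Adjusted over the list alone, these last 7 lists had 12 higher and 7 lower, 7 and 6, 11 and 9, 5 and 3, 5 and 1, 7 and 3, and 10 and 4, in the same order. Of 7 genes specific to a cells, BAR1 (1.29) and ASG7 (0.87) rose, and of 2 measured genes specific to alpha cells SAG1 (0.64) rose (1 in each list when adjusted over the list alone). Of 18 meiosis and sporulation genes, SPO11 (2.09), HOP1 (1.82) and DMC1 (1.04) rose (3 when adjusted over the list alone). ASG7, SAG1 and HOP1 each lost the call without footprint replicate 2 at either concentration, with smallest changes of 0.25, 0.39 and 0.59. ASG7 and SAG1 also lost it without either RNA replicate at 10 µM, and ASG7 without footprint replicate 1 at 0 µM. Both also lost it with DESeq2 and with each assay alone, and ASG7 with library totals and limma voom. Of the 4 strain marker genes, LEU2 rose (1 when adjusted over the list alone).

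**Figure D2:**
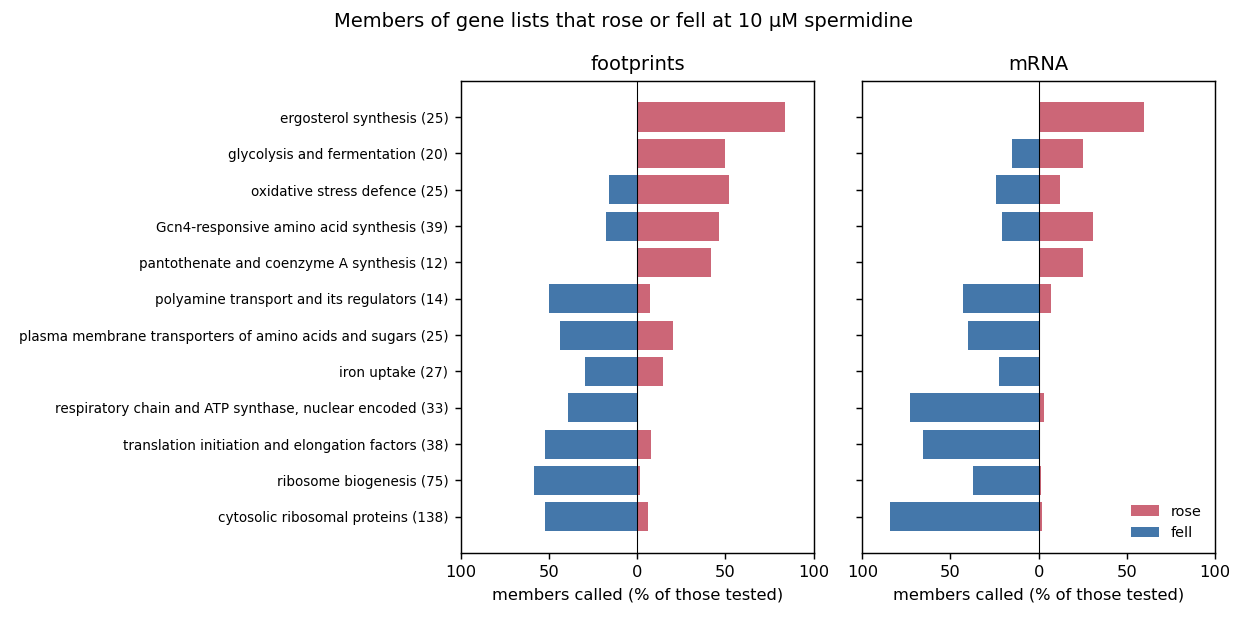
Share of tested members (in %, number tested in parentheses) that rose (red, to the right) or fell (blue, to the left) at 10 µM spermidine in footprints and in mRNA, for 12 of the gene lists. Ergosterol genes rose in 21 of 25 cases in footprints and 15 of 25 in mRNA, and cytosolic ribosomal protein genes fell in 72 and 116 of 138 cases.

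In RNA, 459 genes rose and 734 fell with spermidine, 1193 in all (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). INO1 rose 14.0-fold, from 31.4 ± 2.4 to 440 ± 26 CPM (SD, n = 2; edgeR adjusted p = 8.6e-06). HSP31, a stress-induced chaperone and methylglyoxalase, fell 3.92-fold, from 380 ± 25 to 97.0 ± 4.3 CPM (edgeR adjusted p = 2.7e-05). NCE102, an eisosome protein of the plasma membrane, fell 3.70-fold, from 1298 ± 235 to 351 ± 20 CPM (edgeR adjusted p = 7.1e-05). UGA1 rose 3.40-fold, from 34.6 ± 2.5 to 118 ± 8.1 CPM (edgeR adjusted p = 7.8e-05). The other largest rises were in YPR145C-A (log2 change 2.98), the cell wall gene ZPS1 (2.01), AMS1 (1.99), YER121W (1.89), TDH2 (1.81), SNZ1 (1.8), the meiotic phosphatase regulator gene GIP1 (1.79), SNO1 (1.75), the Rab GTPase gene YPT53 (1.73) and SER3 (1.68). The other largest falls were in YER053C-A (-3.59), AQY2 (-3.41), the cytochrome c oxidase gene COX26 (-2.78), the sulfiredoxin gene SRX1 (-2.38), HXT7 (-2.34), the cell wall mannoprotein gene HPF1 (-2.24), DDR2 (-2.16), YPL277C (-2.01), the cytochrome oxidase assembly gene COA2 (-1.87) and PUT4 (-1.86). YER121W, at 1.1 CPM at 0 µM, lost its call in all 8 omissions of a single library (range 1.68 to 2.07), SNO1 without RNA replicate 1 at 0 µM or either RNA replicate at 10 µM (range 1.53 to 2.03), and HXT7 without RNA replicate 2 at 10 µM (adjusted p 0.065). The excess of falls depended on scaling: 556 genes rose and 618 fell with relative log expression factors, and 531 and 619 with library totals (47.4% and 46.2% higher against 38.5%). The count of 1193 fell to 753 and 661 without RNA replicates 1 and 2 at 10 µM.

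Cytosolic ribosomal protein genes fell in mRNA in 116 of 138 cases and rose in 3 (128 and 3 when adjusted over the list alone; median log2 change -0.63). RPS27A (-1.33) and RPL23A (-1.09) fell, while RPL22B (1.2), RPL9B (1.16) and RPS22B (0.91) rose (camera adjusted p = 4.1e-38 for the list, adjusted p = 0.31 with an estimated correlation). Respiratory chain and ATP synthase genes fell in 24 of 33 cases and rose in 1, NDE2 (1.07; 29 and 1 when adjusted over the list alone; median -0.52), with NDE1 (-1.76), CYC1, cytochrome c (-1.06), and RIP1 (-1.03) lower (camera adjusted p = 3.6e-13, adjusted p = 0.31 with an estimated correlation). The NDE2 call was lost without either RNA replicate at 0 µM or RNA replicate 2 at 10 µM, with a smallest change of 0.48. Translation factors fell in 25 of 38 cases and none rose (29 when adjusted over the list alone; median -0.48), with TIF11 (-1.1), NEW1 (-0.93) and the helicase gene DED1 (-0.78) lower (camera adjusted p = 4.8e-11, adjusted p = 0.31 with an estimated correlation). Ribosome biogenesis genes fell in 28 of 75 cases and rose in 1, RRP12 (0.60; 35 and 1 when adjusted over the list alone; median -0.39), with NOP1, fibrillarin (-0.96), and CBF5 (-0.92) lower (camera adjusted p = 1.5e-06, adjusted p = 0.60 with an estimated correlation). Amino acid and sugar transporter genes fell in 10 of 25 cases and none rose (11 when adjusted over the list alone; median -0.18), with MUP1 (-1.53), GNP1 (-1.19) and the uracil permease gene FUR4 (-1.06) lower (camera adjusted p = 0.0017, adjusted p = 0.31 with an estimated correlation). Genes of the iron uptake list fell in 6 of 27 cases and none rose (6 fell and 1 rose when adjusted over the list alone, median -0.13). Among them were ISU2, a listed gene of iron-sulfur cluster assembly (-1.82), and FET3 (-1.33). The list's call (camera adjusted p = 0.014, adjusted p = 0.31 with an estimated correlation) was lost without RNA replicate 2 at 0 µM, where the median was -0.06.

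Ergosterol genes rose in mRNA in 15 of 25 cases and none fell (17 rose and 1 fell when adjusted over the list alone; median 0.48), again with ERG3 (1.5), ERG6 (1.37), ERG25 (1.3) and ERG26 (1.16; camera adjusted p = 6.8e-12, adjusted p = 0.31 with an estimated correlation). Pantothenate and coenzyme A genes rose in 3 of 12 cases, ECM31 (0.90), CAB2 (0.81) and CAB1 (0.60), and none fell (4 when adjusted over the list alone; median 0.47, camera adjusted p = 0.012, adjusted p = 0.31 with an estimated correlation). All 3 lost their calls without RNA replicate 2 at 10 µM, with largest adjusted p values of 0.059, 0.061 and 0.056, CAB2 also without RNA replicate 2 at 0 µM or replicate 1 at 10 µM. The list lost its call without RNA replicate 2 at 0 µM (median 0.41). Polyamine transport genes fell in 6 of 14 cases and rose in 1 (the same when adjusted over the list alone; median -0.33, camera adjusted p = 0.061). TPO2 (-1.46), TPO4 (-0.69), TPO1 (-0.57), SAM3 (-0.50) and PTK2 (-0.43) were lower besides HOL1, and AGP2 (0.43) was higher. SAM3 lost its call without RNA replicate 1 at either concentration (largest adjusted p 0.068), and TPO1 without RNA replicate 2 at 0 µM or replicate 1 at 10 µM (0.14) and with DESeq2. PTK2 lost it in 5 of the 8 omissions (0.21), and AGP2 in all 8 (0.21). Of 11 other settings, PTK2 lost the call in 7 and AGP2 in 3, DESeq2 and limma voom among them for both. In polyamine synthesis, SPE3 fell from 255 ± 6.7 to 171 ± 9.1 CPM (-0.58, edgeR adjusted p = 0.0035), with SPE2 the other of 2 lower genes. OAZ1 differed by 0.71 without passing (edgeR adjusted p = 0.051; 1 rose and 2 fell when adjusted over the list alone). HYP2 (-0.57) and LIA1 (-0.64) fell among the 4 eIF5A genes (2 when adjusted over the list alone). The lowest value of that list, -1.77, belonged to a member that was not called. HYP2 lost its call without RNA replicate 1 at 0 µM or replicate 2 at 10 µM (largest adjusted p 0.10), and LIA1 without RNA replicate 1 at either concentration (largest adjusted p 0.12). Of the frameshift genes none was called (1 rose when adjusted over the list alone), and of the strain markers SPE2 and URA3 were lower (2 when adjusted over the list alone).

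Gcn4-responsive genes went both ways in mRNA, with 12 of 39 higher and 8 lower (13 and 8 when adjusted over the list alone; median 0.04, camera adjusted p = 0.12), as SER3 (1.68) and ARG1 (1.09) rose and ILV3 (-0.66) fell. Genes with regulatory upstream frames rose in 3 and fell in 7 of 22 (4 and 8 when adjusted over the list alone), with CPA1 (0.86) higher and HAP4 (-1.58) lower. Glycolysis genes rose in 5 and fell in 3 of 20 (6 and 4 when adjusted over the list alone; median 0.07, camera adjusted p = 0.064), with TDH1 (1.37) higher. Heat shock genes rose in 3 and fell in 8 of 30 (6 and 12 when adjusted over the list alone), with SSB1 (-0.86) and SSB2 (-0.80) lower. General stress genes rose in 1 and fell in 7 of 30 (3 and 8 when adjusted over the list alone), with CTT1 (-1.21) and TSL1 (-0.88) lower. Oxidative stress genes rose in 3 and fell in 6 of 25 (the same when adjusted over the list alone), with SOD1 (-0.77) lower. Cell wall genes rose in 4 and fell in 9 of 28 (5 and 9 when adjusted over the list alone), with SCW10 (-1.45) lower and PIR3 (1.2) higher. Methionine genes rose in 5 and fell in 5 of 25 (5 and 6 when adjusted over the list alone), with SAH1 (0.75) higher and SAM1 (-0.79) lower. Nitrogen catabolite genes rose in 5 and fell in 2 of 29. Citric acid cycle genes rose in 4 and fell in 2 of 20, and phosphate genes rose in 3 and fell in 1 of 16. Autophagy genes rose in 2 of 24 and mitochondrial ribosomal protein genes rose in 4 and fell in 2 of 73. Adjusted over the list alone, the last 5 lists had 5 higher and 2 lower, 4 and 2, 3 and 1, none and none, and 1 and 1. Of genes specific to a cells, BAR1 (1.17) and ASG7 (1.41) rose (2 when adjusted over the list alone), ASG7 in only 2 of the 8 omissions of a single library and not with limma voom, and none of the alpha-cell or meiosis genes was called.

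Footprint and mRNA changes went together across genes (Pearson r 0.62). Both were called for 861 genes, of which 350 were higher in both, 497 were lower in both and 14 went in opposite directions. Independent calls would give 85.7 and 146 in the first 2 classes. INO1 rose and HOL1 fell in both assays.

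**Figure D3:**
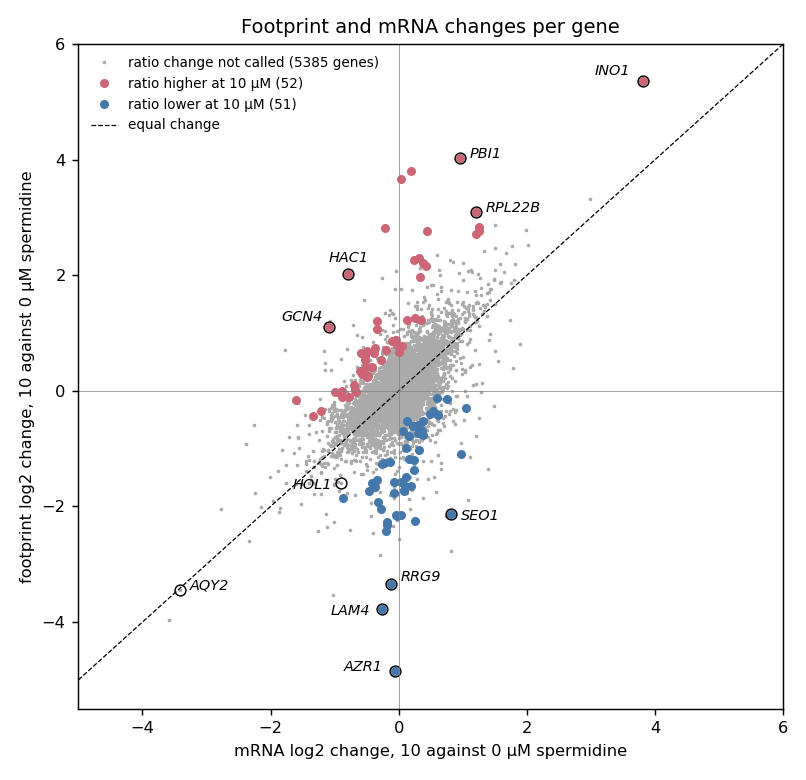
Log2 change in footprints against log2 change in mRNA, 10 against 0 µM spermidine, for the 5488 tested genes. Colored points are the 52 genes whose footprint to mRNA ratio was higher and the 51 whose ratio was lower (adjusted p below 0.05), black circles mark named genes, and the dashed line marks equal change. AZR1, LAM4 and RRG9 lie far below the line near an mRNA change of 0, and GCN4 and HAC1 lie above it with lower mRNA.

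Translational efficiency, tested as the interaction of assay and spermidine in 1 model of all 8 libraries, rose for 52 genes and fell for 51, 103 of 5488 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). GCN4, the transcription activator of amino acid synthesis whose own translation is held back by upstream open reading frames, had fewer mRNA reads and more footprints with spermidine. Its mRNA fell from 1066 ± 17 to 503 ± 9.3 CPM and its footprints rose from 61.3 ± 0.31 to 131 ± 7.7 CPM (SD, n = 2), which raised the ratio from 0.0575 to 0.261, by 2.18 on the log2 scale (SE 0.13, edgeR adjusted p = 6.6e-05). HAC1, the transcription factor of the unfolded protein response, whose unspliced mRNA is held from translation, behaved alike. Its mRNA fell from 812 ± 122 to 469 ± 48 CPM, footprints rose from 39.1 ± 8.9 to 161 ± 14 CPM, and the ratio rose from 0.0496 to 0.343 (log2 change 2.82, SE 0.23, edgeR adjusted p = 6.6e-04). The HAC1 efficiency call was lost by limma on log2 ratios (adjusted p 0.053). The fall of HAC1 mRNA (-0.79) alone was lost without RNA replicate 2 at 10 µM (adjusted p 0.059). In the other direction, LAM4 efficiency fell 11.4-fold, the ratio going from 2.08 to 0.183 (log2 change -3.52, SE 0.18, edgeR adjusted p = 2.5e-05), while its mRNA, 96.8 ± 0.28 and 81.0 ± 3.0 CPM, differed by -0.26 without passing. AZR1 (-4.78) and RRG9 (-3.22) fell likewise, with edgeR adjusted p values of 6.6e-04 and 7.4e-04.

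The genes whose efficiency change held in all 8 omissions of a single library were, besides GCN4, HAC1, LAM4, AZR1 and RRG9, the ribosomal protein gene RPL22B (1.89), the exocytosis gene SRO77 (2.02), YNR071C (1.98), the permease gene SEO1 (-2.96), the kinesin gene KIP1 (-2.19) and NCA3 (-2.11), 11 of the 24 with the largest rises and falls. By limma on log2 ratios, 5 of the 11 lost the call: HAC1, SRO77, YNR071C, KIP1 and NCA3 (adjusted p 0.053, 0.11, 0.11, 0.077 and 0.053). In simulated libraries limma on log2 ratios recovered 13.4% of 2-fold and 86.4% of 4-fold changes in efficiency, against 71.6% and 97.0% with edgeR. The 5 genes changed by about 4-fold or more, where the simulated gap was small. In that simulation limma on log2 ratios called 70 genes against 124 with edgeR, and in the data 12 against 103. Lower recovery of the simulated size therefore does not by itself account for these losses, whose cause was not tested. The other 13 lost their call in at least 1 omission: HES1 (3.63), RRT5 (3.62), PBI1 (3.09), SPG3 (3.03), URA10 (2.33), BNA2 (1.83) and DSD1 (1.74) among the rises, and YMR158C-A (-2.50), CNM1 (-2.23), YCL042W (-2.14), PEF1 (-2.13), PAI3 (-2.09) and SRD1 (-2.06) among the falls. Each of the 13 lost it without RNA replicate 2 at 10 µM, and for PBI1, YMR158C-A and PEF1 this was the only such library (largest adjusted p 0.070, 0.057 and 0.080). By limma on log2 ratios, all of the 13 but PBI1, YCL042W, PEF1 and SRD1 lost it. HES1, RRT5, URA10, CNM1 and PAI3 also lost it by limma voom, URA10 with DESeq2, and PAI3 with a mean count of at least 100 and with a block by culture. BNA2 overlaps YJR079W and YCL042W overlaps GLK1, so their values are uncertain. INO1 efficiency also rose (1.55, edgeR adjusted p = 0.016), a call lost without RNA replicate 2 at 10 µM (adjusted p 0.076) and by limma on log2 ratios. The count of 103 fell to 18 without RNA replicate 2 at 10 µM and to 52 without replicate 1, to 46 and 61 without footprint replicates 1 and 2 at 0 µM, and to 40 and 39 without footprint replicates 1 and 2 at 10 µM. With library totals in place of the composition-adjusted scaling, 37 genes were higher and 83 lower (30.8% higher against 50.5%).

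Most efficiency calls came with a footprint change of the same sign. Of the 52 higher genes, 38 had higher footprints and 21 lower mRNA, with median log2 changes of 0.76 and -0.34. Of the 51 lower genes, 48 had lower footprints and 9 higher mRNA, with medians of -1.49 and 0.10. Because the ratio is built from both assays, such a share is high with no effect: the footprint change had the sign of the efficiency change for 95 of the 103 genes (92.2%), and for 100% of the 100 leading genes in simulated unchanged libraries. Across genes, footprint and efficiency changes correlated with r of 0.67 (0.735 simulated) and mRNA and efficiency changes with r of -0.16 (-0.706 simulated).

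Cytosolic ribosomal protein genes had higher efficiency in 10 of 138 cases and lower in none (18 when adjusted over the list alone; median log2 change 0.33). RPL22B (1.89), RPP2B (1.23), RPL1B (1.19), RPL12A (0.96), RPL42A (0.89), RPS27A (0.89), RPS25B (0.87), RPS9A (0.81), RPS9B (0.77) and RPL12B (0.74) were called, most of them members of duplicated pairs. RPL22B kept its call in all 8 omissions, and the 9 others each lost it without RNA replicate 2 or footprint replicate 2 at 10 µM (largest adjusted p from 0.076 to 0.20) and by limma on log2 ratios. RPL42A, RPS25B and RPS9B also lost it with library totals, RPL42A, RPS9B and RPL12B with the length trend removed, and RPL42A in 4 more settings, relative log expression factors and limma voom among them. The list passed with the preset correlation (camera adjusted p = 1.1e-14) and not with an estimated one (adjusted p = 0.89 with an estimated correlation). Lists of glycolysis (median 0.37, camera adjusted p = 1.5e-05), oxidative stress defence (0.35, 0.0012), ergosterol synthesis (0.31, 4.2e-04), respiratory chain (0.26, 0.0014), Gcn4-responsive genes (0.24, 0.0033) and heat shock proteins (0.22, 0.027) also passed the list test towards higher efficiency, with at most 1 called gene each. Their adjusted p values with an estimated correlation were 0.89 to 0.95. With fry, none of these 7 efficiency calls held (smallest adjusted p 0.10). The respiratory chain call was lost without RNA replicate 1 at 0 µM (median 0.18) or RNA replicate 2 at 10 µM (0.17). The Gcn4-responsive call was lost without RNA replicate 1 at 10 µM (0.13), footprint replicate 1 at 0 µM (0.19) or footprint replicate 2 at 10 µM (0.13), and that of heat shock proteins without the same 3 libraries (0.22, 0.17 and 0.20) and with library totals.

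Single members of the remaining lists were called for efficiency. ARO2 (0.93) of the Gcn4-responsive list, GPM1 (0.68) of glycolysis and the S-adenosylmethionine permease gene SAM3 (0.74) of polyamine transport were higher, and RRP12 (-0.73) of ribosome biogenesis, SDH4 (-0.83) of the citric acid cycle and BAP3 (-1.80) of the amino acid transporters were lower. All 6 lost the call without RNA replicate 2 at 10 µM, either footprint replicate at 0 µM or footprint replicate 2 at 10 µM, with largest adjusted p values of 0.12, 0.14, 0.13, 0.12, 0.16 and 0.16 in that order. All 6 also lost it by limma on log2 ratios, SAM3 and GPM1 with library totals, SAM3 with relative log expression factors and DESeq2, RRP12 and GPM1 with the length trend removed, SDH4 with a mean count of at least 100, and BAP3 by limma voom. Adjusted over the list alone, the counts higher and lower were 3 and 0 for Gcn4-responsive genes, 4 and 0 for glycolysis, 1 and 2 for polyamine transport, and 0 and 1 each for ribosome biogenesis, the citric acid cycle and the transporters. They were 7 and 1 for the respiratory chain, 3 and 0 for methionine genes, 2 and 2 for translation factors and 2 and 2 for genes with upstream frames, of which only GCN4 was called over all genes. Strain markers had 2 and 0, and polyamine synthesis, pantothenate and nitrogen genes had 1 and 0 each. SPE3 (0.19), OAZ1 (-0.03), LEU2 (0.39) and URA3 (0.44) had no called difference in efficiency. No member was called over all genes in the lists for polyamine synthesis, eIF5A, pantothenate, methionine, frameshift, translation factor, general stress, iron, phosphate, nitrogen, autophagy, cell wall, mating type, meiosis, strain marker or mitochondrial ribosomal protein genes. Efficiency differences of the 4 eIF5A genes, none called, ran from 0.07 to 2.48. Unadjusted p values below 0.05 were found for 1018 of all 5488 genes.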

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

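The tests of overlapping genes, of noise in the RNA libraries and of Gcn4 targets were chosen only after the result was seen, as were the lists for the unfolded protein response and the removal of the length trend. Spermidine had opposite called effects on footprints and mRNA in 14 genes, and in 13 of them the difference itself passed the interaction test (edgeR adjusted p below 0.05). Of these, 7 had more footprints on less mRNA: HAC1 (difference 2.82 on the log2 scale), GCN4 (2.18), RPP2B (1.23), the NAD synthesis gene NMA1 (1.14), the permease chaperone gene SHR3 (0.94), the aspartate aminotransferase gene AAT2 (0.84) and RPL12B (0.74). The other 6 had fewer footprints on more mRNA: the DNA damage checkpoint gene RAD9 (-0.89), the tRNA dihydrouridine synthase gene DUS3 (-0.89), ACF4 (-0.91), MFB1 (-1.04), SRD1 (-2.06) and SEO1 (-2.96). The remaining gene, NDE2, differed by -2.97 without passing (edgeR adjusted p = 0.064). Only HAC1, GCN4 and SEO1 kept the call on the difference in all 8 omissions of a single library, HAC1 losing it by limma on log2 ratios (adjusted p 0.053), and the other 10 lost it without RNA replicate 2 at 10 µM and in at least 3 further omissions. DUS3 lost it in all 8. By limma on log2 ratios these 10 but SRD1 lost it as well. The footprint call of RPL12B was kept in 2 of the 8 omissions and lost with library totals and DESeq2, and the mRNA call of SRD1 was lost with DESeq2. The fall in HAC1 mRNA (-0.79) was lost without RNA replicate 2 at 10 µM (adjusted p 0.059), and the rise in SEO1 mRNA (0.82) without RNA replicate 1 at 10 µM (adjusted p 0.051).

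HAC1 stood out because its product drives genes that can be read in the same libraries. If more Hac1 protein was made, genes of endoplasmic reticulum folding and degradation that it activates should be higher in mRNA. Their median mRNA change was 0.639 over 13 genes, with 8 called higher, among them EUG1 (1.41), FPR2 (1.2) and LHS1 (0.84), and none lower. The other 5 were not called: SIL1, HRD1, HRD3, SCJ1 and the chaperone gene KAR2, a well-known target, which differed by 0.19 (edgeR adjusted p = 0.22) in mRNA and rose by 0.44 in footprints (edgeR adjusted p = 0.0086). More active Hac1 at 10 µM may explain the members that rose, as a hypothesis, and leaves KAR2 mRNA unexplained. These values describe the list and do not test the hypothesis, since the list was chosen on these data. The spliced form of HAC1 mRNA was not measured.

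GCN4 was treated alike. The median mRNA change of the 39 Gcn4-responsive genes was 0.0425 (95% interval over genes -0.124 to 0.225; camera adjusted p = 0.12), with 12 called higher and 8 lower, so the data leave open whether more Gcn4 protein acted, and members such as SER3 (1.68), ARG1 (1.09) and ILV3 (-0.66) went apart. Both genes have much RNA at 0 µM and few footprints relative to that RNA, 61.3 ± 0.31 CPM for GCN4 and 39.1 ± 8.9 for HAC1 (SD, n = 2). The ratio of GCN4 changed through footprints (1.1) and mRNA (-1.08) about equally, and that of HAC1 more through footprints (2.03) than mRNA (-0.79).

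A further pattern was the group of 51 genes with lower efficiency at 10 µM, led by AZR1, LAM4 and RRG9. Reads shared with overlapping genes are argued against as the cause for most of the group, since 7.84% of the 51 genes (4 of them) overlap another annotated gene. The share among all tested genes was lower, 2.28%, so this cause stays open for those 4. Overlaps outside the annotated spans were not covered. Gene length bias, with length taken as the annotated span on the genome, is argued against too. After a trend with span was removed from each library, 88.2% kept at least 80% of their change. Noise in the shallower RNA libraries would put the change in the RNA, yet the median footprint change was 111% of the median efficiency change. The median mRNA change was 0.10. These medians place the change of the group mostly in footprints. The genes were chosen on the ratio, which favors footprint changes of the same sign even with no effect. The medians therefore cannot tell which single calls rest on noise in the RNA libraries. A difference in where the ribosomes sat also stays open, since counts without positions cannot show it. So does a biological effect of spermidine on these mRNAs, which may differ from gene to gene and was not tested further.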

How the results depend on the processing

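The removal of a length trend was chosen after the result was seen; the other alternatives were fixed before. In footprints (2118 genes called), every scaling, filter and tool kept the count within 1.5 times, from 1479 with DESeq2 to 2264 with each assay alone; it was 1265 at an adjusted p below 0.01 and 462 with at least a 2-fold change, and ran from 1395 to 2235 when each library was left out. In RNA (1193 called), the same alternatives gave 840 with DESeq2 to 1208 with factors within each assay, with 603 at the stricter threshold, 205 with a 2-fold change and 661 to 1085 over the omissions. In efficiency (103 called), they gave 84 with a mean count of at least 100 to 137 with DESeq2, with 19 at the stricter threshold, 67 with a 2-fold change, 12 by limma on log2 ratios and 18 to 145 over the omissions; the lowest was without RNA replicate 2 at 10 µM, and the cause was not tested beyond the smaller number of libraries. All 12 genes called on log2 ratios were among the 103. DESeq2 gave no adjusted p for 213 genes, which were left out of its counts.

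With the replicate number as a block within each assay, 2453, 1430 and 282 genes were called in footprints, RNA and efficiency, and with footprint and RNA libraries of a condition and number paired as a culture, 166 were called in efficiency. The labels do not say what the numbers mark. Deviations of same-numbered libraries correlated across genes with r of 0.152 between the RNA groups, 0.214 between the footprint groups and 0.032 to 0.121 across assays, which with 2 numbers does not show that they pair the samples.

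Among the named genes and the lists, no called value changed sign under any alternative. Other called genes were not checked for this, and sign changes of values not called under either setting were counted as the same. Over all pairs of a named gene and an alternative, a call was lost in 126 pairs in footprints, 155 in RNA and 259 in efficiency, and gained in 10, 9 and 84. No scaling moved the median of all genes by more than 0.1 on the log2 scale or turned the median of a list that was called. With library totals only, heat shock proteins lost their efficiency call (camera adjusted p 0.053). The replicate block added 2 list calls in footprints and 2 in efficiency. Omissions of a single library both added and ended list calls in each contrast. Estimated correlations ended every list call, and fry, which does not compare a list with other genes, ended all 7 efficiency calls and 1 in RNA, and added 13, 8 in footprints and 5 in RNA.

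In simulated libraries of the same depths, 9.0% of 1.5-fold changes in efficiency were recovered against 40.3% in footprints. Depth, the number of libraries and the larger variance of a difference between 4 groups were not told apart as the reason. A gene such as HOL1, with a difference of -0.70 on the log2 scale, is nearer in size to these than to the 2-fold changes, of which 71.6% were recovered.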

Other observations

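The lists for the kynurenine pathway, histones, endoplasmic reticulum and phospholipids were chosen after the data were seen, so a list p-value on the same data would be circular and none is given for them. Genes of the kynurenine and nicotinamide adenine dinucleotide pathway had more footprints with spermidine, 6 of 10 called higher and none lower (median log2 change 0.54). BNA1 (1.94), BNA6 (1.85) and BNA4 (1.46), enzymes that make nicotinic acid mononucleotide from tryptophan, rose, as did BNA2 (2.20), whose reads overlap those of YJR079W. In mRNA, BNA1 (1.49), BNA6 (1.39) and BNA4 (1.34) also rose, and BNA2 differed by 0.37 without passing (edgeR adjusted p = 0.17). The list had 4 higher and 1 lower (median 0.51). Core histone genes went the other way: 8 of 10 members, the 8 genes for H2A, H2B, H3 and H4, fell in footprints (median -0.93) and in mRNA (median -1.08). The H1 gene HHO1 and the H2A.Z gene HTZ1 differed by -0.25 and -0.09 in mRNA without passing. HTA2 (-1.38) and HHF1 (-1.28) had the largest falls in footprints. Core histone genes come in near-identical pairs, so how reads were divided within a pair is uncertain.

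Genes of endoplasmic reticulum folding and degradation rose in footprints in 10 of 13 cases and fell in none (median 0.83), with EUG1 (1.7), FPR2 (1.27), PDI1 (1.12) and ERO1 (0.99) among them. Their efficiency had a median difference of 0.08 and no called gene.

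INO1 rose more than any other gene in both assays. A general rise of inositol- and choline-responsive genes would raise the other phospholipid genes in mRNA, but their median was -0.0613 (95% interval over genes -0.119 to 0.198, 13 genes), with OPI3 (1.04) and CHO2 (0.34) called higher and none lower. In mRNA these 13 genes did not rise as a whole, while OPI3 and CHO2 did. The list was chosen on these data and its interval treats genes as independent. It therefore cannot decide whether a smaller group of such genes rose with INO1. In footprints 5 of the 13 rose (median 0.24), led by OPI3 (1.2).

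Cytosolic ribosomal protein genes fell in mRNA and had higher efficiency as a group (median 0.33) with the preset correlation. With an estimated correlation neither call held (adjusted p 0.31 in mRNA and 0.89 in efficiency). Against other genes of the same annotated span on the genome, the median efficiency change of these genes stood 0.221 higher (95% interval over genes 0.188 to 0.251, 138 genes). Gene span is thus argued against as the whole cause. The span includes introns, so it can exceed the length of the mRNA. Efficiency changes fell with span across genes (Spearman rho -0.218). A bias by mRNA length therefore stays open. Reads shared between paralogs are argued against as the cause for the 20 single-copy members, which stood 0.296 above the median of all genes (0.205 to 0.346). That comparison was not matched for length, so part of the 0.296 may go with length. Both intervals treat genes as independent, while the estimated correlation of the list in efficiency was 0.52. They are therefore too narrow and do not cover differences between libraries. The cause was not tested further. A trend that links lower mRNA to a higher ratio through the shared RNA libraries stays open, because mRNA and efficiency changes correlated at r = -0.706 across genes in simulated libraries with nothing changed. In the data that correlation was -0.161.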
